A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

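RNA was sequenced from asynchronous, exponentially growing fission yeast (Schizosaccharomyces pombe) in rich YES medium. Per the labels' protocols, 3 cultures received estradiol at 1 µM for 3 h and 3 control cultures received the ethanol vehicle, and the series design calls them biological triplicates. Ribosomal RNA was removed before TruSeq RNA libraries were made for paired-end MiSeq sequencing, per the labels' protocols. This kit does not mark strand, so reads from a gene and from an antisense partner cannot be told apart.

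The authors deposited FPKM values (fragment counts scaled by gene length and library total), one per gene and library, with replicates kept apart. CASAVA 1.4, TopHat2 and Cuffdiff are named, per the submitters' processing notes, with no role or settings. The genome build, the annotation and any scaling between libraries are not given in the sources used here. FPKM divides by the total of each library, so a fall in a few abundant classes raises the values of all others. Cuffdiff-type values can also split reads between near-identical genes, so single members of copied families are uncertain.

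The condition number in the table's column names was matched to that in the sample titles, and the titles' treatment labels gave the groups. The labels' replicate numbers could not be tied to columns. The table numbers its columns 0 to 2 within each group, and libraries are named here by those numbers. Deviations from the group means correlated across genes at 0.152, 0.212 and 0.146 between control and estradiol libraries of the same number, against -0.149 to -0.011 for other pairs. Deviations cancel out over the libraries of a group, so the negative values largely follow from the positive ones and are no separate contrast. The labels do not say what libraries of the same number share. The column number was still used as a block in an alternative fit that was added after the data were seen. The larger counts of calls with the block are thus no independent support.

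The table holds no counts, so the absolute depth is unknown and no counting interval can be given. The spacing of values in genes with a mean FPKM below 2 gave relative depths. Against control library 0, set to 1, they were 1.3 and 0.894 for control libraries 1 and 2, and 0.687, 1.15 and 0.721 for estradiol libraries 0, 1 and 2. Between 462 and 599 features per library were listed at 0. A listed 0 can be a failed estimate, so no fold is given against a group at 0.

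Of 7016 features, 6166 had a mean FPKM of at least 1 over the 6 libraries and were tested, and 850 were not. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend and no covariates, 2-sided, with Benjamini-Hochberg adjustment. A gene is called higher or lower at an adjusted p under 0.05, with no fold minimum. Changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Standard deviations (SD) are over 3 libraries per group. Standard errors (SE) are those of limma's log2 change and rest on its moderated spreads, which draw on all genes. On simulated data with 6166 genes in 6 libraries, limma recovered 18.4% of genes changed 1.25-fold, 68.8% at 1.5-fold, 84.8% at 2-fold and 96.4% at 4-fold, with 4 to 10 false calls per simulation. The simulation changed 200 genes and drew normal noise independently for each gene, from limma's moderated spreads. It held no deviations shared between genes, so recovery and false calls in the real libraries may differ.

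Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over all lists with at least 5 tested genes. Of 38 lists, 35 were tested and 3 were too small. Camera with an estimated correlation and limma's fry were alternatives. Single values per library were compared by exact permutation, whose smallest p for 3 against 3 is 0.1.

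The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, in each direction, the 12 called genes with the largest change whose estradiol values all lie on one side of the control values. It adds the 3 members with the smallest p of each called or main list, plus act1, nda2, nda3, ura4, leu1, ade6 and any transgene. The main lists are core stress genes, chaperones, oxidative stress genes, multidrug transporters, ergosterol genes, ribosomal protein genes and reference genes. The alternatives were other pseudocounts, filters and scalings, no intensity trend, protein-coding genes only, a 2-fold minimum and each library left out in turn. Trend corrections for level, GC content and exon length, and the column-number block, were added after the data were seen.

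Gene names, classes, positions and sequence came from the ASM294v3 reference, to which 6845 of the table's identifiers matched and 171 did not. The authors' build may differ, so coordinates are given only for sequence matches made here on ASM294v3. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for sequence searches and figures.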

Results

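The series measured RNA in fission yeast cultures with and without estradiol, and its title concerns a promoter switched on by estradiol. The comparison asks which transcripts differ after 3 h with 1 µM estradiol in 3 libraries, against 3 control libraries. The labels do not describe the strain, its activator or its reporter. The deposited values are FPKM and their absolute depth is unknown. Relative depth ran from 0.687 in estradiol library 0 to 1.3 in control library 1.

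GFP, the green fluorescent protein, rose with estradiol from 147 ± 15.3 to 714 ± 141 FPKM (mean ± SD, n = 3 per group). The log2 change was 2.26 with an SE of 0.16 and a limma adjusted p of 0.00158, and all 3 estradiol libraries lay above all 3 control libraries. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. GFP stayed called when any library was left out, with adjusted p between 6.03e-04 and 0.0156. The uracil gene ura4 was listed at 0 in all 6 libraries.

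Beyond GFP, estradiol libraries differed from controls in many genes by mostly small amounts. Of 6166 genes tested by limma, 251 were called higher and 241 lower, with median log2 changes of 0.67 and -0.45. Among them, 58 rose and 13 fell by at least 2-fold. Protein-coding genes gave 160 higher and 222 lower of 4903, and long non-coding RNAs (lncRNAs) of the reference gave 75 higher and 17 lower of 1091. All 492 called genes had estradiol libraries on one side of the controls, which a small p nearly requires and which adds no support to the calls. Over all tested genes this held for 31.2%, against 10% by chance. With the column number as a block, 506 were called higher and 524 lower, of which 488 were also called without it. Quantile normalization called 144 and 108. Leaving out control library 0 gave 66 higher and 40 lower, control 1 gave 70 and 37, control 2 gave 160 and 194, estradiol 0 gave 242 and 207, estradiol 1 gave 49 and 39, and estradiol 2 gave 118 and 88. Of the 9 other ways to split the 6 libraries into 3 and 3, none called more than 1 gene in a direction.

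Among the 12 called genes with the largest increases were GFP, hot13 and several lncRNAs. SPNCRNA.834 rose from 1.47 ± 0.48 to 14.2 ± 4.14 FPKM (log2 change 2.61, adjusted p = 0.00421) and SPNCRNA.1436 from 33.4 ± 2.13 to 150 ± 10.9 FPKM (2.13, adjusted p = 1.42e-04). The size for SPNCRNA.834 depends on the pseudocount, with a log2 change of 3.20 at 0.1 and of 1.55 at 5, and at 5 it lay below those of GFP (2.23), SPNCRNA.1436 (2.01), SPNCRNA.942 (1.79) and SPNCRNA.906 (1.69). SPNCRNA.942 rose from 51.1 ± 10.2 to 188 ± 25.7 FPKM (1.87, adjusted p = 0.00307) and SPNCRNA.906 from 193 ± 14.3 to 647 ± 167 FPKM (1.71, adjusted p = 0.00667). SPNCRNA.423 was listed at 0 in every control library and at 8.81, 5.16 and 14.5 FPKM with estradiol. hot13 rose from 10.9 ± 2.66 to 88.0 ± 55.0 FPKM (2.75, SE 0.41, adjusted p = 0.0151), and its call was lost without control 0, control 1 or estradiol 1, with a highest adjusted p of 0.0608.

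Among the 12 called genes with the largest decreases were pho84, pho1, vht1, gdh1, gdh2, rps2202, rps1401, mfm2, SPBC19C7.04c and the lncRNA SPNCRNA.1345. pho84, a phosphate transporter gene, fell from 522 ± 153 to 165 ± 46.2 FPKM (log2 change -1.66, SE 0.25, adjusted p = 0.0153). The biotin transporter gene vht1 fell from 265 ± 58.4 to 108 ± 22.5 FPKM (-1.29, adjusted p = 0.0157). The glutamate dehydrogenase genes gdh2 and gdh1 fell with log2 changes of -1.13 (adjusted p = 0.00237) and -1.07 (adjusted p = 0.0126). SPCC330.03c fell from 38.2 ± 2.73 to 15.9 ± 1.68 FPKM (-1.22, adjusted p = 0.0024). SPNCRNA.1345 (-1.34, adjusted p = 0.0282) and SPBC19C7.04c (-1.24, adjusted p = 0.0279) fell as well, with calls lost without control 0, control 1 or estradiol 1 (highest adjusted p = 0.0995) and without any library but estradiol 1 (0.0868). SPMIT.09, a mitochondrial entry, was listed at 23.3, 33.7 and 23.7 FPKM in the controls and at 0 in every estradiol library. The call of pho84 was lost without control 0 or estradiol 1 (highest adjusted p = 0.0659), that of vht1 without control 1 or estradiol 1 (0.0681), and that of gdh1 without estradiol 1 (0.0552).

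**Figure D1:**
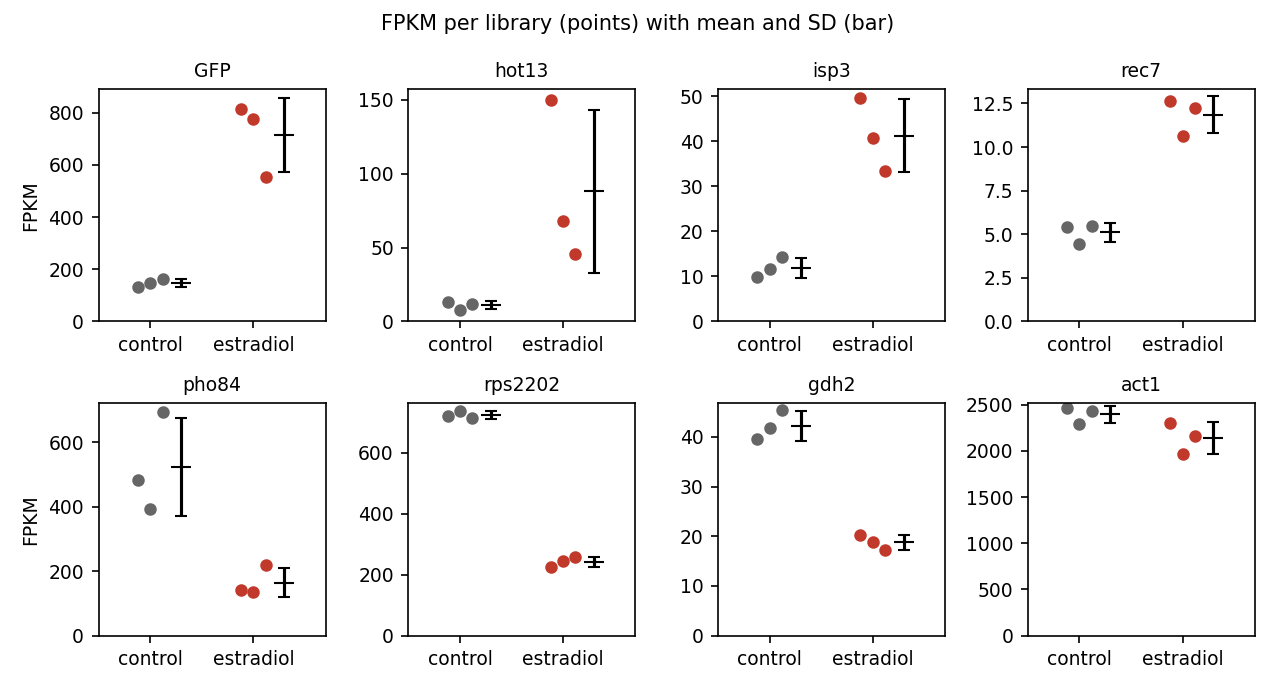
FPKM of 8 genes in each control and estradiol library (points), with the group mean and SD (bar, n = 3 per group); every vertical axis starts at 0. GFP, hot13, isp3 and rec7 were higher with estradiol, pho84, rps2202 and gdh2 were lower, and act1 was not called.

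Many ribosomal protein genes fell. Of 141 tested, 62 were called lower and 0 higher, and 111 lower when adjusted over the list alone, with a median log2 change of -0.37. The list was drawn by gene name and also holds rpp1, rpp21 and rpp40, which are named as ribonuclease P subunits and were not called. rps2202 fell from 723 ± 12.1 to 242 ± 15.6 FPKM (log2 change -1.58, SE 0.06, adjusted p = 1.42e-04), rps1401 from 641 ± 44.0 to 285 ± 17.2 FPKM (-1.16) and rpl1603 from 94.4 ± 4.86 to 48.2 ± 1.05 FPKM (-0.95). Each of these genes belongs to a family of similar copies that can share reads, and the log2 change of the other rps22 copy, rps2201, was -0.28 (adjusted p = 0.125). The list was called by camera (adjusted p = 1.32e-39), but not with an estimated correlation (adjusted p = 0.454). The number of members called lower was 105 with the block, 10 under quantile normalization and 19 after correction for level, with medians of -0.10 under quantile normalization and -0.18 after the correction. It was 7, 6, 10 and 16 without control 0, control 1, estradiol 1 and estradiol 2, but 84 without control 2 and 43 without estradiol 0.

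Factors that assemble ribosomes did not fall with the ribosomal proteins. Of 53 ribosome biogenesis genes, 2 were called higher and 0 lower, also when adjusted over the list alone, with a median log2 change of 0.18. imp4 and utp15, whose products act in the small-subunit processome, rose with log2 changes of 0.61 (adjusted p = 0.0157) and 0.35 (adjusted p = 0.0185), while gar1 had -0.34 (adjusted p = 0.0506, and 0.0119 with the block). Camera gave an adjusted p of 0.00823, and an adjusted p of 0.937 with an estimated correlation. The block called 20 members higher and 1 lower, and 6 were called higher without estradiol 0. The list was not called without control 0, estradiol 1 or estradiol 2 (medians 0.10, 0.13 and 0.13, adjusted p = 0.133, 0.14 and 0.108), and imp4 and utp15 each lost their calls without those libraries (highest adjusted p = 0.0681 and 0.0686), utp15 also without control 1.

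Many genes of amino acid synthesis fell. Of 52 tested, 25 were called lower and 0 higher, and 33 lower and 3 higher when adjusted over the list alone, with a median log2 change of -0.31. ilv5, an enzyme gene of branched-chain amino acid synthesis, fell from 2149 ± 28.0 to 1317 ± 68.0 FPKM (log2 change -0.71, SE 0.07, adjusted p = 0.0049). The lysine synthesis genes lys4 (-0.65, adjusted p = 0.00486) and lys1 (-0.63, adjusted p = 0.00558) fell alike, and these calls and that of gdh2 held without any single library. Under quantile normalization ilv5 had -0.39 (adjusted p = 0.032) and lys4 -0.43 (adjusted p = 0.0141), both still called. The list's adjusted p was 6.21e-15 by camera, and the adjusted p was 0.454 with an estimated correlation. The number called lower was 10 under quantile normalization (median -0.19), 15 after correction for level (median -0.19), and 9, 9, 8 and 12 without control 0, control 1, estradiol 1 and estradiol 2. It was 20 without control 2 and 25 without estradiol 0.

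Some histone genes and some genes of the phosphate regulon also fell. Of 11 histone genes, 5 were called lower, 6 were not called, and 7 were called lower when adjusted over the list alone, with a median log2 change of -0.30. They included hht1, from 935 ± 36.7 to 682 ± 40.9 FPKM (-0.46, adjusted p = 0.0157), and hta1 (-0.37, adjusted p = 0.0271). By camera the adjusted p was 3.16e-05, and the adjusted p was 0.454 with an estimated correlation. Under quantile normalization the histone list was not called (median -0.13, adjusted p = 0.0881). The block called 8 members lower, and limma called 0 after correction for level, under quantile normalization or without control 0, control 1 or estradiol 1, 1 without estradiol 2, 2 without control 2 and 3 without estradiol 0. The list made for the phosphate regulon shares pho4 with that made for the thiamine regulon. Of its 9 genes, 3 were called lower and 4 when adjusted over the list alone, with a median log2 change of -0.19. Beside pho84, these were the acid phosphatase gene pho1, from 182 ± 85.7 to 68.0 ± 8.29 FPKM (-1.32, adjusted p = 0.0431), and vtc4 (-0.70, adjusted p = 0.0197). The other 6 were not called, among them tgp1 (0.52, adjusted p = 0.143) and aps1 and pho7 (both 0.00 after rounding), which are named after their values were seen. Camera gave an adjusted p of 0.0183, and an adjusted p of 0.642 with an estimated correlation. The phosphate list was not called without estradiol 0 (adjusted p = 0.0559), and 0 members were called lower without control 0 or estradiol 1, 1 without control 1, and 2 lower and 1 higher without estradiol 0. The number called lower was 2 without estradiol 2 and 3 without control 2. The call of hht1 was lost without control 0, control 1 or estradiol 1 (highest adjusted p = 0.06), that of vtc4 without the same libraries (0.0681), that of pho1 without any library but control 2 (0.118), and that of hta1 without any but estradiol 0 (0.0967). Under quantile normalization hht1 had -0.22 (adjusted p = 0.117), hta1 -0.17 (adjusted p = 0.174) and pho1 -1.29 (adjusted p = 0.0569), and these 3 calls were also lost after correction for level, that of pho1 also without the filter on low values or the intensity trend.

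Some genes of meiosis and sporulation were higher in these growing cells. Of 43 tested, 6 were called higher and 1 lower, 36 were not called, and 14 were called higher and 2 lower when adjusted over the list alone, with a median log2 change of 0.30. isp3, a spore surface protein gene, rose from 11.96 ± 2.24 to 41.3 ± 8.08 FPKM (3.26-fold, SE of the log2 change 0.18, adjusted p = 0.00595). mde7 rose from 29.4 ± 1.14 to 60.8 ± 2.34 FPKM (1.02, adjusted p = 0.00118) and rec7, a meiotic recombination gene, from 5.11 ± 0.56 to 11.9 ± 1.06 FPKM (1.07, adjusted p = 0.00739). These 3 calls held without any single library. spo4 was the member called lower (-0.43, adjusted p = 0.0358), and mei2, among those not called, had -1.49 (adjusted p = 0.0973). Both are named after their values were seen. The number called higher was 9 with the block, 4 after correction for level, and 3 under quantile normalization (median 0.16) or without control 0, estradiol 1 or estradiol 2. It was 4 without control 1 and 5 without control 2 or estradiol 0. With a minimum mean of 10 FPKM the median was 0.20. Camera gave an adjusted p of 3.16e-05, and an adjusted p of 0.454 with an estimated correlation.

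More lncRNAs were higher than lower. Of 1170 tested by their identifiers, 87 were called higher and 17 lower, and 102 and 18 when adjusted over the list alone, with a median log2 change of 0.18. SPNCRNA.1220 rose from 10.01 ± 0.26 to 24.4 ± 2.06 FPKM (1.20, adjusted p = 0.00207), and SPNCRNA.568 fell from 131 ± 2.11 to 80.2 ± 3.45 FPKM (-0.70, adjusted p = 0.00237). For the class, camera's adjusted p was 1.82e-05, and the adjusted p was 0.364 with an estimated correlation. The block called 149 higher and 36 lower, and quantile normalization 44 and 13 with a median of 0.03. Without control 0, control 1, estradiol 1 and estradiol 2, 30, 31, 22 and 41 were called higher. Without control 2 and estradiol 0, 62 and 84 were called higher. Most lncRNAs (1030) overlap another annotated gene, whose reads this kit cannot separate, and after correction for level, GC content and length the median was 0.07. With a minimum mean of 10 FPKM it was 0.11.

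**Figure D2:**
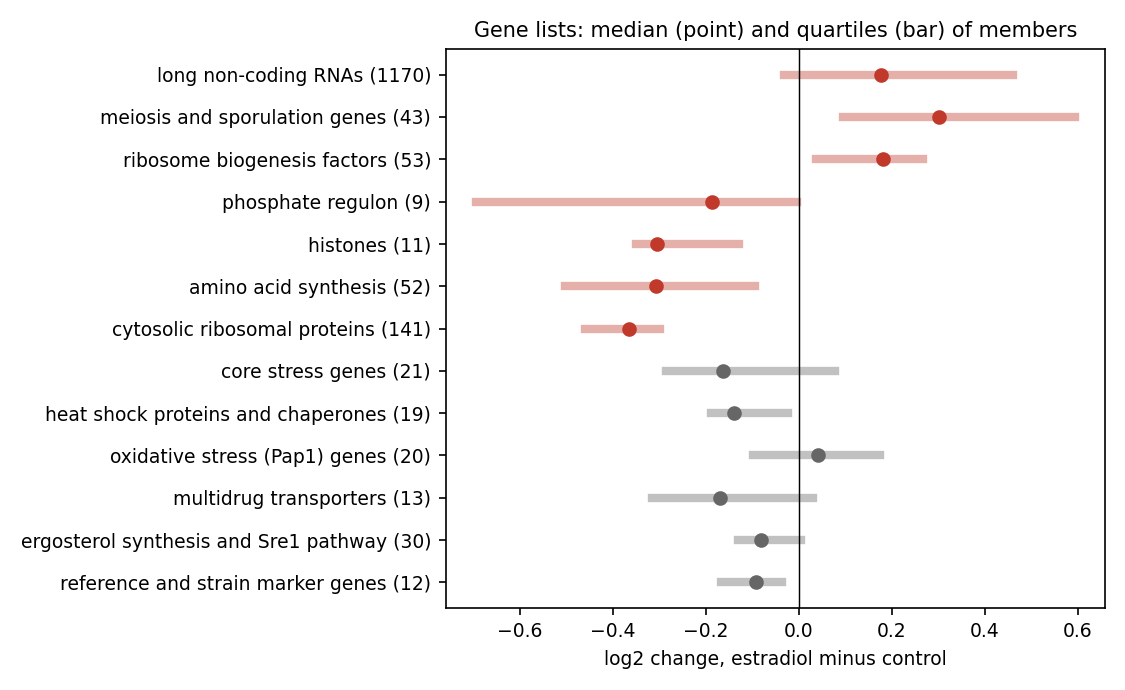
Median (point) and quartiles (bar) of the log2 change, estradiol minus control, over the tested members of the called and the main gene lists, with the number of members in brackets; red marks lists called by camera at the preset correlation. The medians of lncRNAs, meiosis genes and ribosome biogenesis genes lie above 0, and those of ribosomal protein, amino acid synthesis, histone and phosphate genes below 0; with an estimated correlation camera called 0 lists, and 2 had an unadjusted p under 0.05.

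The lists of stress and drug-response genes were not called, beside 492 called genes of 6166 tested overall. Among 21 core stress genes, pcr1 (log2 change -0.41, adjusted p = 0.0208) and the catalase gene ctt1 (-0.49, adjusted p = 0.0271) fell and 19 were not called (list adjusted p = 0.179). Among 19 chaperone genes, hsp20 rose (0.79, adjusted p = 0.0352), hsp90 (-0.32, adjusted p = 0.0331) and mcp60 (-0.46, adjusted p = 0.0271) fell, and 16 were not called (list adjusted p = 0.061, and 0.0329 lower with the block). Of 20 oxidative stress genes only ctt1 was called (list adjusted p = 0.886), and tpx1 had -0.41 (adjusted p = 0.0668, and 0.0183 with the block). Of 13 multidrug transporter genes only abc4 was called (-0.23, adjusted p = 0.0461; list adjusted p = 0.272), and the block also called abc1 (0.55, adjusted p = 0.00548) and fnx2 (-0.40, adjusted p = 0.0239). The largest changes among the transporter genes were those of bfr1 (0.81, adjusted p = 0.268) and mfs3 (-0.70, adjusted p = 0.511), which were not called. gst2, bfr1 and mfs3 are named after their values were seen. Of 30 ergosterol genes limma called 0, and 4 had an unadjusted p under 0.05 (list adjusted p = 0.0679, and 0.0267 lower with the block). The block called erg28 (-0.44, adjusted p = 0.026) and fps1 (-0.19, adjusted p = 0.039) lower, and srk1 among the core stress genes (-0.57, adjusted p = 0.0289). Under quantile normalization fps1 had a log2 change of 0.01 and was not called by limma (adjusted p = 0.93). In all the block called 6 core stress genes lower, 2 chaperone genes higher and 4 lower, 2 oxidative stress genes higher and 3 lower, 2 multidrug genes higher and 4 lower, and 4 ergosterol genes lower. When adjusted over the list alone, the numbers called were 3 core stress, 5 chaperone, 1 oxidative stress, 2 multidrug and 0 ergosterol genes. hsp90 and abc4 lost their calls without any library, with highest adjusted p of 0.119 and 0.143. Those of pcr1, mcp60 and hsp20 were lost without any but estradiol 0 (0.0851, 0.099 and 0.114), and that of ctt1 also held without control 2 (highest 0.0883). Under quantile normalization the calls of hsp90 (-0.01, adjusted p = 0.936), mcp60 (-0.41, 0.0513), hsp20 (0.78, 0.0568) and abc4 (-0.22, 0.081) were lost. Those of hsp90, mcp60 and abc4 were also lost after correction for level, and those of hsp20 and abc4 without the intensity trend, hsp20 also without the filter on low values.

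Of the 12 reference and marker genes, 2 were called lower and 0 higher. The actin gene act1 had a log2 change of -0.17 (adjusted p = 0.274), the tubulin genes nda2 and nda3 0.07 and -0.08 (adjusted p = 0.56 and 0.479), leu1 0.20 (0.412) and ade6 -0.10 (0.563). Under quantile normalization act1 and nda3 had 0.09 and 0.11 (adjusted p = 0.59 and 0.222), and both were also above 0 under each trend correction. lys1 (-0.63, adjusted p = 0.00558) and arg3 (-0.35, adjusted p = 0.0443) were called lower, also when adjusted over the list alone (list adjusted p = 0.0997). When a library was left out, the call of arg3 held only without control 2 (highest adjusted p = 0.135). It was also lost under quantile normalization (-0.37, adjusted p = 0.0568), after correction for level, and without the intensity trend or the filter on low values. his7 had 0.19 (adjusted p = 0.107) and was called higher with the block (adjusted p = 0.0419) and under quantile normalization (0.37, adjusted p = 0.0194).

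Markers of mating type and of other cell states did not move together. Since the labels do not describe the strain, its mating type is not known here. The P-cell genes mam2, map2 and map3 had log2 changes of 0.14, -0.12 and 0.21 with 0 called by limma. Of the M-cell genes, mfm2 fell (-1.32, adjusted p = 0.0428), mam1 had -0.41 (adjusted p = 0.0749), and mfm3 and ste6 had 0.20 and 0.02. mfm1, listed at 0 in 1 library of each group, had -0.07 (adjusted p = 0.956). The call of mfm2 was lost when any library was left out (highest adjusted p = 0.135), under quantile normalization (-1.35, adjusted p = 0.0569), after correction for level, and without the intensity trend or the filter on low values. The mating list (adjusted p = 0.272) and the stationary-phase list (0.886, median -0.08 and mean 0.09) were not called. Of 26 mating genes, mfm2, sxa1 (-0.38, adjusted p = 0.0283) and mam4 (-0.40, adjusted p = 0.0385) were called lower. Of 12 stationary-phase and spore-like markers, isp3 and fbp1 (0.88, adjusted p = 0.0185) were called higher and pas1 (-0.52, adjusted p = 0.0105) lower. sxa1, mam4, fbp1 and pas1 are named after their values were seen. The nitrogen starvation list was not called either (0.0997, and 0.00984 lower with the block). In all, 7 of 35 lists were called at the preset correlation, 3 higher and 4 lower, and 28 were not. With an estimated correlation camera called 0 lists. Leaving out estradiol 0 called 14 lists, and other splits of the 6 libraries into 3 and 3 called up to 16.

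The shares of gene classes in the summed FPKM were compared by exact permutation, whose smallest p here is 0.1. Ribosomal protein genes took 27.1 ± 1.74% of it in controls and 22.7 ± 0.66% with estradiol, and non-coding RNA genes 5.78 ± 0.14% and 7.43 ± 0.46%, each with an exact permutation p of 0.1. The sum itself was 831139 to 876214 in controls and lower, 767792 to 798655, with estradiol. The shares are thus linked, and a fall in one class raises those of others. Mitochondrially encoded genes took 4.08 ± 0.59% and 4.91 ± 1.41% (exact p = 0.6), and the 10 highest genes 10.7 ± 0.82% and 12.9 ± 1.30% (exact p = 0.2). The mean Pearson correlation across genes was 0.965 within groups and 0.959 between groups (exact permutation p = 0.1), and over pairs of libraries Pearson's r ran from 0.949 to 0.977 and Spearman's rho from 0.964 to 0.984.

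**Figure D3:**
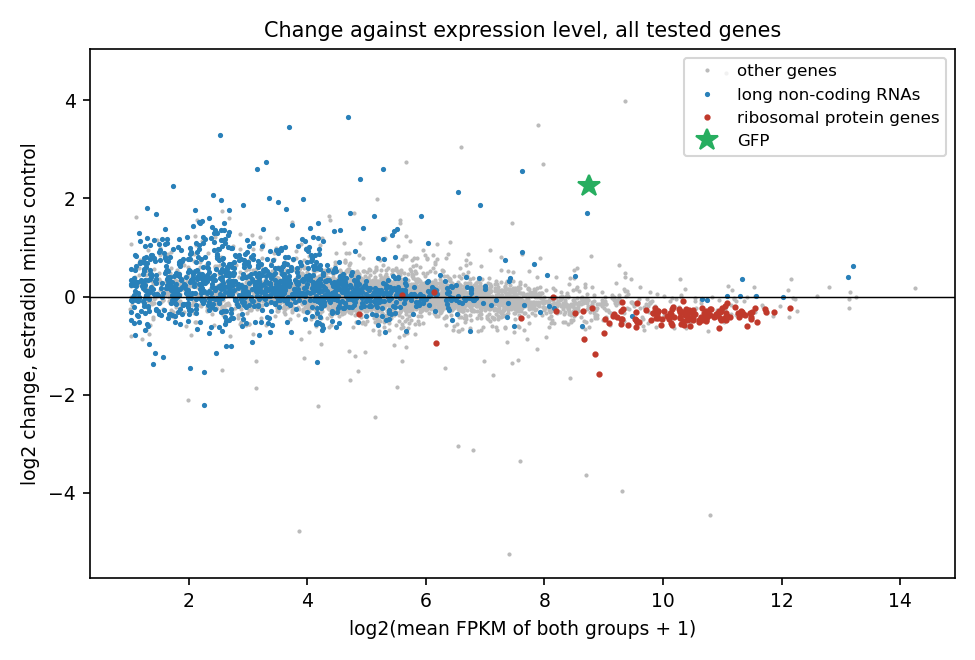
Log2 change, estradiol minus control, of each tested gene (6166) against its log2(mean FPKM + 1) over both groups. Ribosomal protein genes (red) lie at high levels and mostly below 0, lncRNAs (blue) at low levels with a median of 0.18, and GFP (star) at 2.26.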

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

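The block by column number and the trend corrections were chosen after seeing the data. No paired analysis was possible by the labels' numbers because the columns carry none; the column numbers were used instead. Pseudocounts, filters on low values, median ratio scaling, dropping the intensity trend and testing protein-coding genes only kept the counts of genes higher and lower within 1.5 times of 251 and 241. Quantile normalization gave 144 higher and 108 lower, and 236 of those calls were among the original ones. The replicate block gave 506 higher and 524 lower, and 410 higher with the level, GC and length correction or 422 with the level correction, which then called 11 lists. Without the block, those corrections gave 160 and 131 lower. A minimum log2 change of 1 left 58 and 13 by construction. With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, while fry called 2 higher and 3 lower. Leaving out each library in turn gave 49 to 242 genes higher, 37 to 207 lower and 6 to 14 lists, with fewer libraries in each fit. Apart from these, the causes were not tested. Of the 61 named genes, 46 were called. Over 1191 combinations of gene and setting, 1005 kept their side of the threshold, 151 lost the call and 35 gained one. The sign changed in 11 of them, all of genes not called (act1, nda3 and fps1), and in 0 of called genes. Of the called ones, 22 stayed called whichever library was left out and 17 in every setting. The block changed the calls of 8 named genes, all gained, and called 3 further lists, given above. The depth behind each value is unknown, so a gene not called may have changed by less than these libraries can show. In simulation with noise independent between genes, 18.4% of the smallest changes made were recovered.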

Other observations

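Tests of the Zif268 counts, the ribosomal copies, the corrections for level, GC content and length, added background and the Mmi1 motifs were chosen after the results were seen, as were the gene groups of the next paragraph. Tests of exact and near Zif268 sites by their median and of lncRNAs that overlap no gene were set before their results were seen, as were the counts over other splits. The test of lncRNAs over lower genes was set before its own result but after the other lncRNA values.

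Among enzymes that charge transfer RNAs and that make nucleotides, some were lower with estradiol. The groups in this paragraph were chosen after the results of these same libraries were seen, so their camera p-values are no independent support. Of 32 aminoacyl-tRNA ligase genes, 9 fell and 0 rose, with a median log2 change of -0.15 (camera p = 3.48e-07, and p = 0.104 with an estimated correlation), and -0.07 after correction for level, GC content and length (camera p = 2.50e-04). vrs1 fell from 405 ± 21.8 to 291 ± 13.3 FPKM (-0.47, adjusted p = 0.0128) and lrs1 from 376 ± 28.9 to 261 ± 16.2 FPKM (-0.52, adjusted p = 0.0151). Of 18 purine and pyrimidine synthesis genes, 6 fell and 0 rose, with a median of -0.18 (camera p = 2.51e-07, and p = 0.037 with an estimated correlation), and -0.10 after that correction (camera p = 7.07e-04). ura1 fell from 740.4 ± 52.1 to 505 ± 4.08 FPKM (-0.55, adjusted p = 0.00914) and ade10 by a log2 change of -0.57 (adjusted p = 0.0129). Of 98 mug and meu genes, named for higher expression in meiosis and outside the meiosis list, 9 rose and 0 fell, with a median of 0.14 (camera p = 0.00156, and p = 0.0115 with an estimated correlation), and 0.07 after it (camera p = 0.0362). mug37 rose from 5.85 ± 1.03 to 18.8 ± 4.05 FPKM (1.52, adjusted p = 0.00958).

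A hypothesis is that an activator recognising the Zif268 site, GCGTGGGCG, acts at some sites in the yeast genome. Zif268 is the DNA-binding part of one kind of estradiol-dependent activator, and the labels do not say which activator these cells held. The planned test could not be run, since 0 protein-coding genes have the exact site within 500 bases upstream. With at most 1 mismatched base, 39 genes have a site, and their median log2 change exceeded that of the other 4864 genes by 0.017 (permutation p = 0.632). This difference met the outcome set beforehand as going against the hypothesis. The bound behind that outcome was judged wrongly chosen afterwards, because a median over 39 genes cannot show a few active sites. Among these 39, 7 were called higher and 1 lower, or 17.9% higher against 3.15% of the others (153 genes; Fisher's exact p = 2.20e-04). The same search with the 251 other orders of these 9 bases gave 0 to 14.3% (median 3.23%), so the site exceeded 100% of them. Their base composition is equal, and the orders share similar sequences, so they are not independent. The count of 7 was noticed in these same libraries, so the tests of it, here and under other settings, are no independent support.

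The 7 genes were inp53, isp3, ned1, csn71, SPAC4G9.19, SPCC24B10.20 and SPBC530.11c, named after their values were seen. inp53 rose from 32.2 ± 1.83 to 72.0 ± 2.96 FPKM (log2 change 1.14, adjusted p = 0.00118) and has its site at chromosome I 1991118 to 1991126 (ASM294v3), 13 bases from the annotated start. ned1 (0.96, adjusted p = 0.00597) and csn71 (0.79, adjusted p = 0.0287) share 1 site at chromosome I 4991079 to 4991087, so 6 of 37 distinct sites lie beside a gene called higher. That of SPAC4G9.19 (1.20, adjusted p = 0.0182) lies 47 bases upstream, at chromosome I 2287096 to 2287104. Over 9 other settings (quantile normalization, the block, a trend correction and each library left out), 3 to 10 genes with a site were called higher, with Fisher's exact p from 2.08e-04 to 0.00722. Of the 4 exact sites, all inside genes on chromosome I, that at 826973 to 826981 lies in SPNCRNA.689, which rose from 15.8 ± 0.54 to 52.2 ± 13.6 FPKM (1.63, adjusted p = 0.00623), and in uba42 (0.19, adjusted p = 0.504). Another lies in SPAC23D3.13c (0.44, adjusted p = 0.0129), and the others in rps601 (-0.44, adjusted p = 0.0196) and dri1 (-0.16, adjusted p = 0.299). Binding was not measured, and a strain without the activator was not used here.

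For the fall of ribosomal protein genes, the values argue against reads moving between copies as the whole cause. Whether a trend over level is the whole cause is not settled. The 22 genes counted as single-copy had a median log2 change of -0.31 (SD 0.06 over estradiol libraries, 3 called). The summed values of all 56 families counted as copied had log2 changes below 0. Copies were grouped by gene name alone, so the 22 include rpp21 and rpp40, and the rpp1 and rpl8 families may each mix unlike genes. Removal of the trend over level (62 to 19 genes called lower) took the median from -0.37 (SD 0.03) to -0.18 (SD 0.07; camera adjusted p = 1.24e-18, and adjusted p = 0.674 with an estimated correlation), and removal of GC content and length as well gave -0.19. A fall of abundant genes could thus carry about as much of the change as remains, or all of it, and only 49 other genes lie at these levels (median -0.20). The SD values here leave out the spread between controls. For the share of summed FPKM in these genes, that spread was the larger (SD 1.74% in controls, 0.66% with estradiol). What remains after correction is therefore not shown to exceed the spread between libraries. A response of the cells to estradiol or to the induced proteins remains open and untested, since the design holds no estradiol-treated strain without the system.

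For the higher lncRNAs, reads of overlapping genes cannot account for the 79 that overlap no gene annotated in ASM294v3. Their median log2 change was 0.47 without correction for level, GC content and length (SD 0.18 over estradiol libraries, 8 higher and 1 lower). That SD leaves out the spread between controls, and the authors' annotation may differ. For the 1030 that do overlap a gene (median 0.17), reads of overlapping genes cannot be told apart as a cause. The 298 whose overlapping genes all had a log2 change below 0 still had a median of 0.055 (SD 0.04). That is above the bound of 0 set for this test, but the bound left out the trend over level. The corrected median was -0.004 (SD 0.03). Correction for level, GC content and length lowered the class median from 0.18 (SD 0.06) to 0.071 (SD 0.02; camera adjusted p = 0.0196, and adjusted p = 0.323 with an estimated correlation), so those trends may carry most of it. Whether they carry all of it is not settled, since these SD values also leave out the spread between controls. An equal added background, such as genomic DNA, also stays open. Protein-coding genes of mean FPKM 1 to 10 gained 0.464 of the FPKM that lncRNAs of that level gained (0.517, 0.520 and 0.408 by library).

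Another hypothesis is that RNAs bound by Mmi1, a protein that directs meiotic transcripts to destruction in growing cells, were removed less. It was formed after mei4, mug4 and mug37 were seen to be higher, and the motif limit was set from motif counts in known targets. After correction, 35 protein-coding genes with at least 6 TNAAAC motifs in 500 bases changed by 0.227 more than the other 4868 (SD 0.05 over estradiol libraries; permutation p = 1e-04, the smallest the resamples can give, with genes not independent). Without the 3 genes that prompted it, the difference over 32 genes was 0.205 (SD 0.03; permutation p = 1e-04), and only fft3 was called higher. The meiosis genes among them were also known to be higher, and the 22 outside that list differed by 0.09 (permutation p = 0.0335), less than the 0.15 that the hypothesis was set to require. The 32 meiosis genes without such motifs had a corrected median of 0.16 with 5 called higher, so the hypothesis stays open.

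The 6 libraries can be split into 3 and 3 in 10 ways, so no share of splits can fall below 0.1. The real split called 251 genes higher and 241 lower and the others at most 1 in a direction, so 1 of 10 splits gave as many in either. For gene lists, 6 of the 10 splits called as many as the 7 of the real one or more, up to 16 lists. The list calls at the preset correlation are thus no larger than other splits give. Among the 4 splits that part all 3 column numbers, the others called up to 10 lists and at most 1 gene.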
